A study of Mus musculus with 4 samples.

How the data were processed

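The labels describe 4 ATAC-seq libraries of pachytene spermatocytes from mouse testis, 2 from a Znhit1 knockout and 2 from controls, and name 2 independent biological replicates. Groups were taken from the genotype label. Per the labels' protocols, isolated nuclei were cut with Tn5 and more than 30000000 reads were obtained per sample. The submitters' processing notes name cutadapt 2.5, Bowtie2 2.3.4.3, Picard 2.20.7, MACS2 2.2.4 and the genome build mm10. The role of each tool, the peak calling threshold, any shift of reads for the Tn5 cut and any filter on duplicates or mitochondrial reads are not given in the sources used here.

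The authors deposited peak lists, and 2 were analysed here, 1 recorded for the first knockout library and 1 for the first control library. Whether each list was called on 1 library or on both replicates of its genotype together is not given in the sources used here, and the remaining 2 libraries were not analysed here. Each deposited list has 3 columns, the chromosome, start and end of each peak, and no header, height, fold, p or q value or summit. The knockout list had 29656 lines and the control list 24167. Many intervals stood on several lines, and each was counted once, which left 21004 and 15376 peaks, of which 6091 and 6016 had been listed more than once. MACS2 can list an interval once per summit, but the lists do not say whether that is the reason. Since the number of reads behind each list is unknown, a longer list can come from a deeper or better enriched library as well as from more open sites.

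Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The chance level came from 100 random circular shifts of the counted list along each chromosome, with the other list left in place (seed 1). Such shifts also move peaks off gene ends, so this level does not allow for both lists favouring gene ends. Shares carry Wilson 95% intervals for counting error only, and neighbouring peaks are not independent. No test between genotypes was run, because there is 1 list per genotype.

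Genes came from a RefSeq gene table of GRCm38.p6, whose primary chromosomes are those of mm10, with gene starts, ends and types but no strand, transcripts or exons. A gene-end peak is a peak within 1 kb of either annotated end of a protein-coding gene. This replaces the promoter window and the exon and intron classes that were planned before the data were examined, and a peak assigned to a gene may lie at its 3' end, belong to a neighbour or miss an alternative promoter. Positions are 1-based. The 14 gene lists were fixed before the data were examined. They cover the SRCAP and H2A.Z machinery, the chromosome axis and synaptonemal complex, meiotic recombination, meiotic sex chromosome inactivation and the DNA damage response, pachytene transcription regulators, the piRNA pathway, the meiotic divisions, spermiogenesis, spermatogonia, Sertoli cells, Leydig, peritubular, endothelial and immune cells, housekeeping genes, developmental regulators and X-linked spermatid genes. Of their 333 entries, 332 matched the gene table, by symbol or synonym, and stand for 331 different genes. Each list's counts were set against 10000 random lists. For the number with a peak these were drawn from all protein-coding genes, and for the number in 1 peak list alone from the genes with a peak.

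The genes and peaks named were chosen by a rule fixed before the data were examined. It takes Znhit1 first, up to 4 members per gene list with a peak in 1 peak list alone, the 10 leading gene-end peaks of each genotype alone (predicted gene names skipped), the 5 leading peaks of each list and of each genotype-only class, and the 3 widest peaks of each list. The rule ranked peaks by -log10 q. As the lists hold no such value, peaks were ranked by width instead, so wide peaks are over-represented among the names. A genotype-only gene was named only if its peak did not overlap any peak of the other list. At 23 of the knockout-only and 23 of the control-only genes the widest peak did overlap one outside the window. Other members of the gene lists are named as examples of their class, and were chosen after their values were seen.

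The overlap and gene assignment were tested on simulated intervals. All 5126 intervals made to be shared and all 3800 made to be unshared were recovered, bedtools 2.31.1 gave the same 5126, and 200 of 200 genes given a peak at their start were found. The shared intervals were control peaks moved by a small part of their width, and the unshared ones lay in the middle of wide gaps. Slight overlaps and peaks near the edge of a window were therefore not tried. Alternatives fixed before the data were examined were merging peaks within 200 bp, an overlap of 50% of both peaks, a gap of up to 500 bp counted as shared, windows of 500 bp and 3 kb, and a denominator of autosomes, X and Y. Stricter -log10 q thresholds of 5 and 10, the leading peaks by -log10 q and the summit as the point of overlap were planned and not run, since the lists hold no such values. In their place, and chosen after seeing the data, came peaks at least 300 bp wide, the same number of widest peaks from each list, intervals listed at least 2 times and the midpoint in place of the summit. Gene ends of any annotated gene were also added then.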

Results

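Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open chromatin, in pachytene spermatocytes from mouse testis. Pachytene is the stage of meiotic prophase at which homologous chromosomes are fully paired. Cells of a Znhit1 knockout were set against control cells, and the question was how ZNHIT1, a subunit of the SRCAP complex that places the histone variant H2A.Z into chromatin, affects accessible sites at this stage. The labels name 4 libraries, 2 per genotype, with the tag P35 and more than 30000000 reads each. The values analysed here are 2 peak lists, 1 per genotype, which give the position of each peak and no height, score or summit. With 1 list per genotype no difference has a replicate check and no p-value can be given. All intervals quoted are Wilson 95% intervals and cover counting error only. The depth behind each list is not given in the sources used here.

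Znhit1 itself had a peak in both lists. The gene lies on chromosome 5 from 136982194 to 136987959 (mm10), and its peak near the end coordinate of the gene ran from 136986801 to 136987492 in the knockout list and from 136986774 to 136987406 in the control list. The peak was 692 bp wide in the knockout and 633 bp wide in the control, and it also lay within 1 kb of an end of 1 other protein-coding gene. A peak at a gene end does not show whether the deleted part of the gene was present, so it does not check the genotype labels. Among the 14 genes of the SRCAP and H2A.Z machinery, 11 had a gene-end peak in both lists, among them Srcap, the ATPase of the complex, Actr6 and Yeats4, and both H2A.Z genes, H2az1 and H2az2. Anp32e, which encodes a chaperone that removes H2A.Z, had a peak of 313 bp in the knockout list alone (chromosome 3, 95929013 to 95929325). Ruvbl2 and Vps72 had none in either list. With both lists cut to intervals listed at least 2 times, 7 of the 14 genes were in both lists and 2 in the knockout alone.

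The knockout list was longer than the control list and its peaks were narrower. It held 21004 separate peaks covering 9.58 Mb, against 15376 peaks covering 7.85 Mb in the control, a ratio of 1.37 in number and 1.22 in length. The median width was 352 bp in the knockout (quartiles 251 and 585 bp) and 427 bp in the control (quartiles 293 and 657 bp). On all 19 autosomes the knockout list held more peaks than the control list. Peaks under 300 bp numbered 8157 in the knockout and 4067 in the control. When only intervals listed at least 2 times were kept, the lists held 6091 and 6016 peaks, so the larger number in the knockout lay among intervals listed once.

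About 1 in 3 knockout peaks and under 1 in 2 control peaks lay at a site that was also a peak in the other genotype. Of the knockout peaks, 6807 (32.4%, 31.8 to 33.0) overlapped a control peak by at least 1 bp, and of the control peaks, 6829 (44.4%, 43.6 to 45.2) overlapped a knockout peak. When the counted list was itself shifted at random along each chromosome, in 100 shifts, the mean overlap was 0.605% of knockout peaks and 0.823% of control peaks. The shared peaks were the wide ones, with median widths of 695 bp in the knockout and 658 bp in the control, and they held 51.0% and 60.4% of the covered length. The 14197 peaks found in the knockout list alone had a median width of 288 bp, and the 8547 found in the control list alone had one of 326 bp. Over 6296 shared sites where 1 peak met 1 peak, the median log2 ratio of knockout to control width was 0.03, with quartiles of -0.29 and 0.38. With both lists cut to intervals listed at least 2 times, 54.0% of knockout peaks and 54.9% of control peaks were shared. Overlaps with dropped intervals of the other list did not count there, and the shared percentage depends on which peaks are kept.

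**Figure D1:**
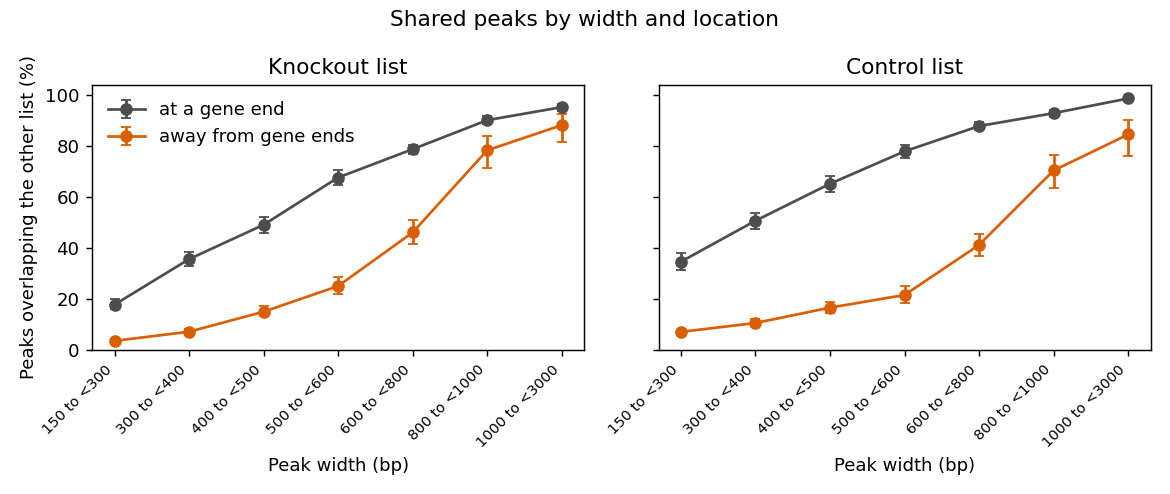
Percentage of peaks that overlap a peak of the other list (vertical axis) by peak width in bp (horizontal axis), for the knockout list (left) and the control list (right), with peaks within 1 kb of an end of any annotated gene in grey, all others in orange, and bars for the Wilson 95% interval. At 600 to 800 bp, 78.8% of knockout peaks at a gene end were shared and 46.1% of those elsewhere.

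Shared accessible sites lay mostly at gene ends, whereas sites found in 1 genotype alone, with all peaks counted, lay mostly elsewhere in the knockout and the control alike. Gene ends are either end of a protein-coding gene with 1 kb to each side, because the annotation used gives no strand and does not tell a promoter from a gene's 3' end. Of the shared peaks, 77.98% (76.98 to 78.95) in the knockout and 78.1% (77.1 to 79.1) in the control lay at a gene end. Of the peaks in the knockout alone, 17.1% (16.5 to 17.8) did, 43.3% lay inside a gene away from its ends and 39.5% lay outside genes. Of the peaks in the control alone, 15.0% (14.2 to 15.7) lay at a gene end, 46.3% inside a gene and 38.7% outside. Over the whole lists, 36.9% (36.2 to 37.5) of knockout peaks and 43.0% (42.2 to 43.8) of control peaks lay at a gene end. This order between the genotypes was turned when the 15376 widest peaks of each list were compared (46.7% and 43.0%) and among intervals listed at least 2 times (71.4% and 69.15%). Among the latter, 54.9% of peaks in the knockout alone and 49.2% of those in the control alone lay at a gene end. Some of these peaks may overlap an interval of the other list that was listed once and so dropped.

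The X chromosome, which is silenced and packed into the sex body in pachytene spermatocytes, held few peaks in either genotype. It carried 132 knockout peaks (0.628% of the list, 0.530 to 0.745) and 107 control peaks (0.696%, 0.576 to 0.840), although it holds 4.41% of protein-coding genes. A gene-end peak was present at 79 of its 966 protein-coding genes in the knockout (8.18%, 6.61 to 10.1) and at 60 in the control (6.21%, 4.86 to 7.91). On the autosomes, 40.3% of 20665 genes had one in the knockout and 34.9% in the control. Whether silencing accounts for the gap between X and the autosomes was not tested. X-linked genes with a peak in both lists included Taf7l, a germ cell TFIID subunit, and Hcfc1, Kdm5c, Ogt and Fmr1, which were chosen after their values were seen. Peaks on X were concentrated at its far end, from the start of Mid1 at 169685199 to the last peak of either list, a stretch of 1.20 Mb that reaches into the pseudoautosomal region where X and Y pair. It held 27 of the 132 knockout peaks and 23 of the 107 control peaks, of which 11 and 6 lay beyond the last annotated gene. The first of them began inside Mid1, at 169969884 in the knockout and 169969813 in the control, and the part of the stretch before them held none. Over the whole stretch there were 22.6 and 19.2 peaks per Mb, against 0.619 and 0.495 per Mb on the rest of X and 8.47 and 6.19 per Mb on the autosomes. The Y chromosome held 27 knockout and 28 control peaks, of which 11 and 10 lay towards its far end. Whether the same sequence was counted on both X and Y was not tested. The interval of the X percentage in the knockout list overlapped that in the control list, and the order of the percentages turned among peaks at least 300 bp wide (0.794% and 0.734%), with equal numbers of the widest peaks (0.709% and 0.696%) and among intervals listed at least 2 times (0.722% and 0.665%).

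**Figure D2:**
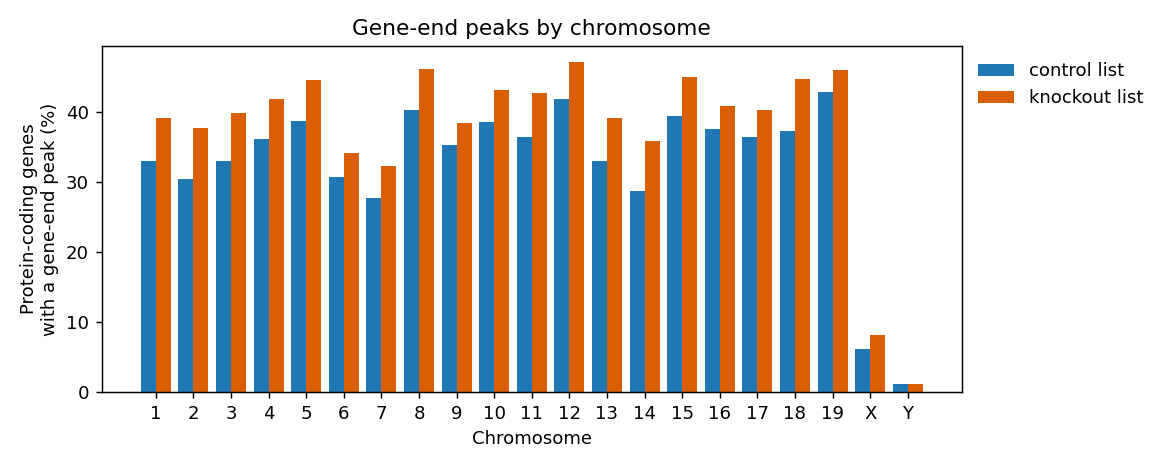
Percentage of protein-coding genes with a peak within 1 kb of an annotated end (vertical axis) on each chromosome (horizontal axis), for the control list (blue bars) and the knockout list (orange bars). On X the bars stand at 6.21% and 8.18%, and on the autosomes as a group the values were 34.9% and 40.3%.

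Most genes with an accessible gene end had one in both genotypes. Of 21887 protein-coding genes, 6255 (28.6%) had a gene-end peak in both lists, 2147 (9.81%, 9.42 to 10.2) in the knockout list alone, 1019 (4.66%, 4.38 to 4.94) in the control list alone, and 12466 in neither. Independent lists would share 2792 genes if each gene were equally likely to have a peak. Gene families differ widely in this, with a peak at 15 of 1110 olfactory receptor genes and 71 of 81 cytosolic ribosomal protein genes. The number 2792 does not allow for such differences. At 6088 of the 6255 genes in both lists the peaks themselves overlapped. Genes found in the knockout alone outnumbered those found in the control alone by 2.11 to 1, and by 1.175 to 1 when only intervals listed at least 2 times were kept. With those intervals, 3472 genes had a peak in both lists, 1687 in the knockout alone and 1436 in the control alone. Genes counted there in 1 list alone may still have a peak listed once in the other.

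The widest gene-end peaks found in the knockout alone lay at Pde3b, a cyclic nucleotide phosphodiesterase (1517 bp; chromosome 7, 114414818 to 114416334), Paip1, a translation factor that binds poly(A)-binding protein (1459 bp; chromosome 13, 119428346 to 119429804), and Npepl1 (1429 bp; chromosome 2, 174109932 to 174111360). Ctbp1, a transcriptional corepressor, had a peak of 1386 bp on chromosome 5 (33274070 to 33275455). Trim44 and Eid1, both on chromosome 2, had peaks of 1373 bp (102399963 to 102401335) and 1363 bp (125672679 to 125674041). Rap1gds1 had a peak of 1318 bp (chromosome 3, 139074478 to 139075795) and Fbxl5, an iron-sensing F-box protein gene, one of 1260 bp (chromosome 5, 43781472 to 43782731). On chromosome 11, the peak of Mafg, a small Maf transcription factor gene, spanned 1252 bp (120632715 to 120633966) and that of Smurf2, a ubiquitin ligase gene, 1244 bp (106920162 to 106921405).

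The widest gene-end peaks found in the control alone lay at Pxdc1 (1457 bp; chromosome 13, 34651883 to 34653339), Prkar1a, a regulatory subunit of protein kinase A (1328 bp; chromosome 11, 109650000 to 109651327), and Wdr5, a core subunit of the MLL and SET1 histone H3K4 methyltransferase complexes (1212 bp; chromosome 2, 27514429 to 27515640). Chst13 had a peak of 1122 bp (chromosome 6, 90308727 to 90309848), Nek10 one of 1077 bp (chromosome 14, 14803883 to 14804959) and Cdon one of 1075 bp (chromosome 9, 35421085 to 35422159). H1f7, the spermatid linker histone gene also called H1T2, had a peak of 1065 bp that covered the end of the gene on chromosome 15 (98256347 to 98257411). Mesp2 had a peak of 1062 bp (chromosome 7, 79810537 to 79811598), Lactbl1 one of 1046 bp (chromosome 4, 136636968 to 136638013), and Zfp526 one of 1023 bp that was shared with another gene's end (chromosome 7, 25219056 to 25220078). A gene-end peak was shared with the end of another gene at 29.9% of the genes with a knockout peak and 31.5% of those with a control peak.

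Genes that act in meiotic prophase had accessible gene ends in most cases, and with all peaks counted more of these were present in both genotypes than in 1 alone. Of 18 genes of the chromosome axis and synaptonemal complex, 9 had a peak in both lists, among them Sycp1, Sycp3, Hormad1 and Smc1b. Another 5 had one in the knockout alone, including the meiotic cohesin gene Rad21l (922 bp), the central element gene Tex12 (846 bp) and Syce2 (578 bp), and 2 had one in the control alone, Fkbp6 (772 bp) being the wider. Of 35 meiotic recombination genes, 20 had a peak in both lists, including Prdm9, which directs recombination to hotspots, Dmc1 and Msh4. The 4 in the knockout alone included Mnd1 (778 bp), Hsf2bp (752 bp) and Mlh3 (587 bp), and Cntd1 (570 bp) was in the control alone. The peaks of Hsf2bp and Cntd1 were shared with another gene's end, and with a window of 500 bp 3 recombination genes were in the knockout alone. Spo11 had none in either list. Of 18 genes of meiotic sex chromosome inactivation and the DNA damage response, 15 had a peak in both lists, among them Brca1, Atr, Mdc1 and H2ax, and Chek1 (934 bp) had one in the knockout alone. With both peak lists cut to intervals listed at least 2 times, the recombination list had 8 genes in both, 8 in the knockout alone and 5 in the control alone. The sex chromosome inactivation and DNA damage list had 6, 5 and 2.

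Genes listed as pachytene transcription regulators were likewise present in both lists for the most part. Not all members of this gene list act at pachytene or on transcription. Of its 21 genes, 16 had a peak in both, including Mybl1, the master regulator of pachytene genes, Tcfl5, Brdt and Meiosin. In the knockout alone there were 2, E2f6 (816 bp) and Stra8 (335 bp). Of 24 piRNA pathway genes, 16 had one in both, including Piwil1, Mael and Ddx4, Tdrd1 (396 bp) in the knockout alone, and Fkbp6 (772 bp) and Tdrd5 (572 bp) in the control alone. Of 25 cell cycle genes of the meiotic divisions, 12 had one in both, including Cdk1, Ccnb1 and Hspa2. Here 3 were in the control alone, the spindle checkpoint and anaphase genes Cdc20 (977 bp), Bub1b (414 bp) and Aurkb (359 bp), and 2 in the knockout alone, of which Bub1 (622 bp) was the wider. With a window of 3 kb the meiotic division genes numbered 4 in the knockout alone and 1 in the control alone, and the order of the piRNA genes turned with the 500 bp window (1 and 0), the 3 kb window (2 and 1) and intervals listed at least 2 times (3 and 2). Among the last, the pachytene regulators numbered 1 and 2, and the genes in both lists were 9 for the piRNA pathway and 7 for the meiotic divisions.

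With the 1 kb window, most members of the lists of somatic cells, spermatogonia, developmental regulators and X-linked spermatid genes had no peak in either genotype. In the spermiogenesis list 21 of 37 had none. Of the 37 spermiogenesis genes, 10 had a peak in both lists, 5 in the knockout alone, among them Tekt2 (723 bp), Spag6 (673 bp) and Pgk2 (327 bp), and 1 in the control alone, H1f7. The Tekt2 peak was shared with another gene's end. The protamine and transition protein genes Prm1, Prm2, Tnp1 and Tnp2 had none in either list. Of 20 spermatogonial genes, 1 was in both lists, Etv5, with 4 in the knockout alone, including Sohlh2 (677 bp) and Foxo1 (480 bp), and 2 in the control alone, Id4 (617 bp) and Dmrt1 (415 bp). Of 18 Sertoli cell markers, none was in both and 2 were in the knockout alone, Dhh (847 bp, a peak shared with another gene's end) and Amhr2 (416 bp), while Sox9, Wt1 and Amh had none. Of 18 markers of Leydig, peritubular, endothelial and immune cells, Acta2 (313 bp) had a peak in the knockout alone and the other genes had none. Of 40 developmental regulators, Olig2 had one in both, 2 were in the knockout alone, with Hoxb1 (418 bp) the wider, and 3 in the control alone, Eomes (350 bp), T (330 bp) and Hoxb9 (289 bp). The peak of T was shared with another gene's end. Of 15 X-linked genes of spermatids, Hmgb3 (501 bp) had a peak in the control alone and the rest had none. Of 29 housekeeping genes, 19 had a peak in both lists, Polr2a (993 bp, a peak shared with another gene's end) in the knockout alone and Gapdh (231 bp) in the control alone. The other 8 had none, among them Actb, B2m and Tubb5, so a missing peak here does not show that a gene end was closed. With both lists cut to intervals listed at least 2 times, 11 housekeeping genes were in both lists, 5 in the knockout alone and 0 in the control alone. With a window of 3 kb, 7 of the 18 markers of Leydig and other somatic cells had a peak (1 in both, 4 in the knockout alone, 2 in the control alone) and 5 of the 18 Sertoli cell markers (1, 2 and 2). Of the 20 spermatogonial genes, 3 were then in both lists, 5 in the knockout alone and 2 in the control alone, so it no longer held that most had none. Spermiogenesis genes in the knockout alone and in the control alone were equal in number with equal numbers of the widest peaks (3 and 3) and among intervals listed at least 2 times (2 and 2, with 5 in both). With a window of 3 kb, 13 of the 37 spermiogenesis genes were in both lists, 7 in the knockout alone and 0 in the control alone, so most then had a peak.

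**Figure D3:**
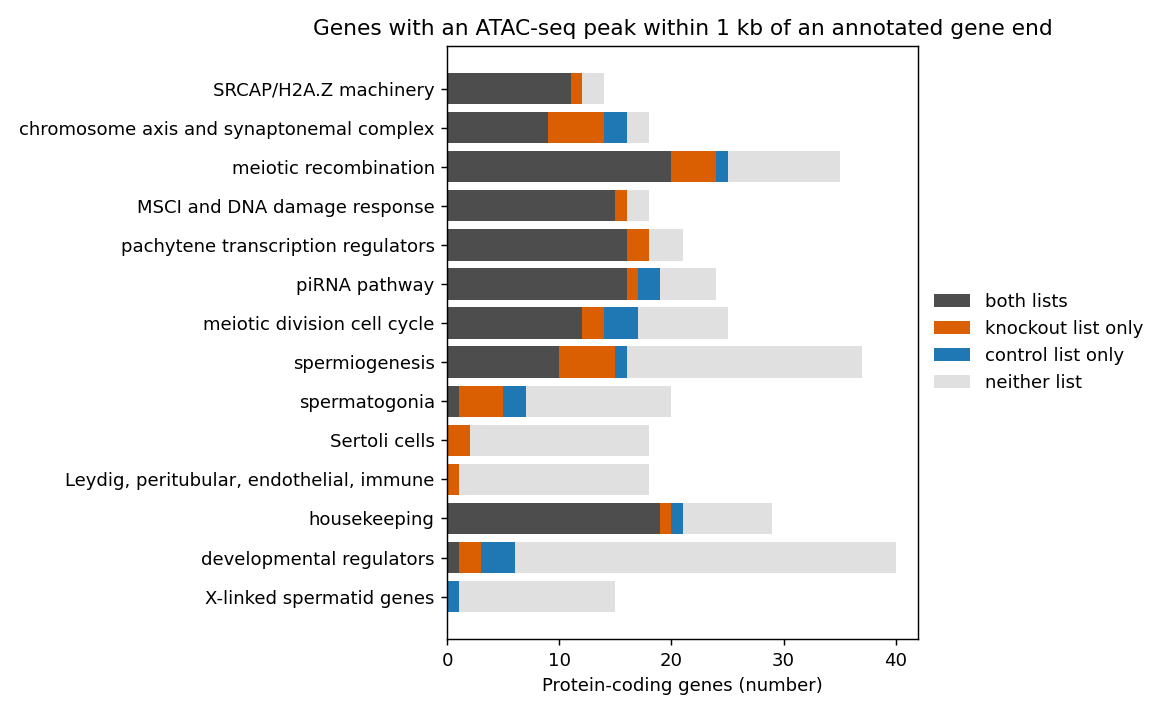
Number of protein-coding genes (horizontal axis) of each of the 14 gene lists (vertical axis) with a peak within 1 kb of an annotated end in both peak lists (dark grey), in the knockout list alone (orange), in the control list alone (blue) or in neither (light grey). MSCI is meiotic sex chromosome inactivation. In the recombination bar 20 of 35 genes are dark grey and in the axis and synaptonemal complex bar 9 of 18, and in the Sertoli cell bar 16 of 18 genes are light grey.

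Against 10000 random lists of as many protein-coding genes, the number of members with a peak in either list lay at the 99.4th percentile for the meiotic division genes and at the 99.9th or above for the housekeeping genes, the SRCAP and H2A.Z machinery and the remaining meiotic and piRNA lists. It lay at percentile 51.7 for spermiogenesis, 23.7 for spermatogonia, 0.175 for Sertoli cells and X-linked spermatid genes, 0.01 for Leydig and other somatic cells, and 0 for developmental regulators. The number in the knockout alone was compared with random genes that had a peak. It lay at percentile 79.1 for the axis and synaptonemal complex, 22.0 for recombination, 5.46 for sex chromosome inactivation and the DNA damage response, 2.69 for the piRNA pathway and 1.995 for housekeeping genes. It lay at 96.6 for spermatogonia and at 97.2 for Sertoli cells, which rests on 2 genes, and between 11.6 and 88.8 for the other lists. The number in the control alone lay at percentile 98.9 for developmental regulators (3 genes), 94.6 for X-linked spermatid genes (1 gene), 89.97 for spermatogonia and 81.5 for the meiotic divisions, and between 6.295 and 61.7 for the other lists. Knockout-only and control-only genes were equal in number for Sertoli cells with a window of 3 kb (2 and 2) and for spermatogonia among intervals listed at least 2 times (2 and 2). For developmental regulators they numbered 1 and 0 with a window of 500 bp and 5 and 4 with 3 kb. These percentiles describe the lists and are not tests. Over all 14 lists, 130 genes had a peak in both, 31 in the knockout alone and 15 in the control alone, and the number in both was 72 when only intervals listed at least 2 times were kept. With a window of 500 bp, 8 genes of these lists were in the control alone.

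The widest peaks of both lists were shared sites. No filter for repeated or poorly mapped sequence was applied to the lists here, so mapping artefacts among these peaks are not excluded. In the knockout, a peak of 2845 bp lay over a predicted gene on chromosome 9 (124422473 to 124425317), one of 2336 bp lay outside genes on chromosome 12 (3235105 to 3237440), with Rab10 the nearest protein-coding gene, and one of 2252 bp lay at the end of Cdk13 on chromosome 13 (17803378 to 17805629). These were followed by peaks at Csf2ra on chromosome 19 (2164 bp, 61225350 to 61227513) and Duxf3 on chromosome 10 (2086 bp, 58231786 to 58233871). In the control, the widest lay at Fcgr3 on chromosome 1 (2378 bp, 171063702 to 171066079), Duxf3 (2200 bp, 58231742 to 58233941) and Nectin3 on chromosome 16 (2077 bp, 46495656 to 46497732), followed by Kdm2a on chromosome 19 (2032 bp, 4396552 to 4398583) and a site inside Muc6 on chromosome 7 (2007 bp, 141637798 to 141639804). Of the 5 widest peaks found in the knockout alone, 4 were those at Pde3b, Paip1, Npepl1 and Ctbp1, and the fifth lay at the end of a predicted gene on chromosome 6 (1385 bp, 149584910 to 149586294). The widest found in the control alone lay outside genes on chromosome 10 (1733 bp, 86590305 to 86592037). After Pxdc1, a predicted gene on chromosome 2 (1366 bp, 165992337 to 165993702) and Prkar1a came a site inside Tulp4 on chromosome 17 (1295 bp, 6232409 to 6233703).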

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

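The minimum width of 300 bp, the equal numbers of widest peaks, the intervals listed at least 2 times, the midpoint and the gene ends of any kind were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because there is 1 peak list per genotype and no test. The planned thresholds and ranks on -log10 q and the summit overlap were not run, since the lists hold no such values, and the denominator of autosomes, X and Y moved nothing because the lists hold no other chromosomes. Values below are given for the knockout and then the control, and the cause of each shift was not tested unless the alternative itself sets it. In each alternative that recomputed them, shared peaks lay at gene ends more often than peaks of 1 genotype alone. Genes with a peak in the knockout alone outnumbered those in the control alone with both windows, 300 bp, equal numbers and intervals listed at least 2 times. Merging peaks within 200 bp could not change any gene count, since a gap that short cannot hold a whole gene-end window. The unknown depth of each list limits every count of peaks.

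With peaks within 200 bp merged, 16.5% of knockout-only peaks lay at a gene end. When 50% of both peaks had to overlap, 26.2% and 35.8% were shared, 79.8% and 79.9% of shared peaks lay at a gene end, and 21.6% and 22.5% of genotype-only peaks did, which turned the order of the last pair. A gap of up to 500 bp gave 34.2% and 46.7% shared, with 76.7% and 76.7% of shared and 16.2% and 13.5% of genotype-only peaks at a gene end. The midpoint gave 29.7% and 41.3% shared, 79.1% of shared control peaks at a gene end, and 19.15% and 17.6% of genotype-only peaks. A window of 500 bp put 33.9% and 39.3% of peaks at a gene end (shared 74.7% and 74.5%, genotype-only 14.3% and 11.1%) and left 8 genes of the fixed lists in the control alone. A window of 3 kb gave 43.8% and 49.96% (shared 83.2% and 83.4%, genotype-only 24.8% and 23.3%), and the ends of any annotated gene gave 42.6% and 48.6% (shared 82.4% and 82.5%, genotype-only 23.55% and 21.4%).

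Peaks at least 300 bp wide numbered 12847 in the knockout, 46.85% and 53.5% were shared, 52.9% and 53.3% lay at a gene end (shared 81.7% and 81.8%, genotype-only 27.55% and 20.6%), and 0.794% and 0.734% lay on X, which turned the order of that pair, as did equal numbers of the widest peaks (0.709% and 0.696%) and intervals listed at least 2 times (0.722% and 0.665%). With equal numbers of the widest peaks, which makes the shared percentages alike by construction, 42.6% and 43.05% were shared, 46.7% of knockout peaks lay at a gene end, above the control's 43.0%, and so did 79.5% and 79.6% of shared and 22.3% of knockout-only peaks. Intervals listed at least 2 times numbered 6091 and 6016, and overlaps with dropped intervals of the other list did not count. Of these 54.0% and 54.9% were shared, 71.4% and 69.15% lay at a gene end (shared 85.45% and 85.5%, genotype-only 54.9% and 49.2%), 3472 genes had a peak in both lists, 72 genes of the fixed lists did, and the ratio of knockout-only to control-only genes was 1.175.

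Of 252 counts for single gene lists under the alternatives, 186 stayed within 1.5 times the reported count. These include all counts with merged peaks, which could not change, and counts that were 0 both times, so the number overstates stability. The order of knockout-only to control-only genes turned in 4 lists. It became 1 to 2 for the pachytene regulators among intervals listed at least 2 times, 1 to 0, 2 to 1 and 3 to 2 for the piRNA pathway with the 500 bp window, the 3 kb window and intervals listed at least 2 times, 4 to 1 for the meiotic divisions with the 3 kb window, and 1 to 0 and 5 to 4 for the developmental regulators with the 500 bp and 3 kb windows. The counts became equal for Sertoli cells with the 3 kb window (2 and 2), for spermatogonia among intervals listed at least 2 times (2 and 2), for spermiogenesis among those and with equal numbers of widest peaks (2 and 2, 3 and 3), and for sex chromosome inactivation and the DNA damage response at 300 bp or wider and with equal numbers of widest peaks (1 and 1 in each). They were 0 and 0 for the somatic list other than Sertoli cells and for the developmental regulators among intervals listed at least 2 times. For housekeeping genes, reported as 1 and 1, they became 1 and 0, 2 and 0, 2 and 0, and 5 and 0 with the 500 bp window, the 3 kb window, 300 bp or wider and intervals listed at least 2 times. With the 3 kb window the somatic list other than Sertoli cells went from 1 of 18 genes with a peak to 7, with 1 in both, 4 in the knockout alone and 2 in the control alone.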

Other observations

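The gene families, gene types and tests in this part were all chosen after the results were seen, and none of them compares replicates.

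Most members of 4 families of genes that every cell uses had a gene-end peak in both genotypes. Of 81 cytosolic ribosomal protein genes, 64 had a gene-end peak in both lists, 4 in the knockout alone and 3 in the control alone, where random genes with a peak gave a median of 16 in the knockout alone. Of 49 genes for subunits of respiratory complex I, 36 were in both, 7 in the knockout alone and 0 in the control alone, where the random medians were 10 and 5. Of 78 mitochondrial ribosomal protein genes, 47 were in both, 15 in the knockout alone, equal to the random median of 15, and 6 in the control alone. Of 51 proteasome subunit genes, 28 were in both, 8 in the knockout alone (random median 9), 3 in the control alone and 12 in neither. Olfactory receptor, cytochrome P450 and Hox genes had few. Olfactory receptor genes had a peak at 15 of 1110, with 2 in both, 5 in the knockout alone and 8 in the control alone, where the random medians of the last 2 were 3 and 2. Cytochrome P450 genes had one at 17 of 99, with 3 in both, 10 in the knockout alone and 4 in the control alone (random medians 4 and 2). Hox genes had one at 7 of 39, with 0 in both, 6 in the knockout alone and 1 in the control alone (random medians 2 and 1). Numbers in the knockout alone above the random median were not particular to these families. They were 11 against 5 for Kcn potassium channel genes (23 of 94 with a peak) and 4 against 2 for keratins (8 of 53). They were 3 against 1 for beta-defensins (3 of 42), 2 against 1 for vomeronasal receptors (4 of 355) and 50 against 44 for Zfp zinc finger genes (194 of 397).

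Each gene type had a peak within 1 kb of an end at a larger share of its genes in the longer knockout list, with 38.4% against 33.2% for protein-coding genes and 8.55% against 5.70% for microRNA genes. For transfer RNA genes it was 124 of 408 (30.4%, 26.1 to 35.02) in the knockout and 76 (18.6%, 15.1 to 22.7) in the control. With the 15376 widest peaks of each list, transfer RNA genes stood at 27.0% (22.9 to 31.5) and 18.6%, and protein-coding genes at 36.5% and 33.2%. With the full lists, 70 transfer RNA genes were in both lists, 54 in the knockout alone and 6 in the control alone. Since such genes lie in clusters, the 54 rested on 37 peaks over 12 chromosomes and the 6 on 5 peaks. Long non-coding RNA genes had a peak at 13.2% in the knockout and 10.4% in the control. Over the autosomes there were 1.66 knockout-only peaks per control-only peak, with the lowest ratio, 1.08, on chromosome 18 and the highest, 2.204, on chromosome 3.

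Peaks away from the ends of any annotated gene were less often found in both lists than peaks at such ends, and peaks away from gene ends were also narrower. Narrow peaks may simply lie near the calling threshold, so peaks of equal width were compared. At 600 to 800 bp, 46.1% (41.3 to 50.8) of knockout peaks away from any annotated gene's ends were shared against 78.8% (76.8 to 80.6) at gene ends, and 41.2% (37.0 to 45.5) of control peaks against 87.8% (86.2 to 89.3). In all 7 width classes and both lists the intervals lay apart in the same direction, with a smaller gap among peaks at least 1000 bp wide (88.2% against 95.3% in the knockout, 84.5% against 98.7% in the control), which argues against width as the whole cause. Peak height is unknown, and genotype, animal and library stay open as causes, since each genotype has 1 list.

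The control list, though shorter, held 8547 peaks that the knockout list lacked. Of its 4596 peaks at least 600 bp wide, 667 (14.5%, 13.5 to 15.6) overlapped no knockout peak, and these lay mostly away from the ends of annotated genes of any kind. There 371 of 791 (46.9%, 43.4 to 50.4) had no knockout peak, against 296 of 3805 (7.78%, 6.97 to 8.67) at gene ends. A deeper or better enriched knockout library could lengthen the knockout list, and whether it could also leave these shares of wide control peaks out was not measured, since that needs 2 lists of 1 genotype. Depth, enrichment, animal and genotype therefore cannot be told apart here as sources of these peaks.

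Peaks of 1 genotype alone that lay away from the ends of annotated genes of any kind, not of protein-coding genes alone, were crowded towards the distal ends of the autosomes. The last 10% of the autosomes held 24.0% (23.2 to 24.8) of those in the knockout and 29.5% (28.4 to 30.6) of those in the control, against 12.5% (12.2 to 12.8) of annotated genes. Positions were scaled to the end of the last annotated gene, so peaks beyond it always count in the last 10%, and genes cannot lie beyond it. Gene density around the peaks was not tested, so it stays open as a cause. Shared peaks away from gene ends stood at 26.7% and 26.9%. Among peaks at least 500 bp wide the values were 34.1% (30.7 to 37.6) and 36.3% (33.1 to 39.6) for 1 genotype alone, above 22.2% (18.9 to 25.8) and 23.2% (19.8 to 26.9) for shared ones, whereas under 500 bp, where most of these peaks lie, they were 23.3% (22.5 to 24.1) and 28.5% (27.3 to 29.6), below 30.9% (27.3 to 34.7) and 30.1% (26.6 to 33.8) for shared ones, with overlapping intervals in the control. A candidate explanation for the wide peaks alone is meiotic recombination hotspots, which PRDM9 opens, which lie more often towards the distal ends of chromosomes in males, and which differ between mice that carry different Prdm9 alleles. It was not decided, because no hotspot map, strain or genome sequence was used here, and the base composition of distal regions was not tested.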
